A study of Mus musculus with 12 samples.

How the data were processed

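Total RNA from the testes of 22-day-old and 28-day-old mice, wild-type or lacking MEIG1, was measured on 12 Illumina bead arrays, with 3 arrays for each of the 4 combinations of genotype and age. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase on RNeasy columns, checked on a Bioanalyzer and amplified to biotinylated cRNA with a MessageAmp kit, giving a measurement in 1 colour. Groups and replicate numbers were taken from the sample titles. Per the labels, all 22-day arrays lay on one chip and all 28-day arrays on another, so chip and age cannot be told apart, and within each chip the wild-type arrays took the leading 3 positions and the mutant arrays the next 3. The labels do not say that the 3 arrays of a group came from separate mice, so every p-value measures only the spread between these samples, which may be technical.

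The table the authors deposited holds linear intensity values for 45281 probes. Its smallest value is -33.5 and about 30.4% of values in each array are at or below 0, which shows that background was subtracted. Its 12 columns share nearly one distribution (sorted values differ between columns by at most 1.3 at any rank, with medians of 24.0 to 24.2 and the same maximum of 54186), so the deposited intensities had already been quantile-normalized. The software used and any filter are not given in the sources used here. Intensities under 16 were set to 16, a floor that held about 45.3% of values in each array, and log2 was taken, so the lowest possible value is 4. A fold against a group with at least 2 of its 3 arrays at the floor is given as "at least N-fold". For arrays, the number of replicates limits the precision.

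Probes were named with GEO's platform annotation and looked up in a table of RefSeq mouse genes (assembly GRCm38.p6). That table held the gene identifier of 34807 probes, and the look-up changed 0 symbols. Exactly 1 symbol was given for 34885 probes, several for 18 and none for 10378, and only those with 1 symbol were used. Each of the 19057 genes was represented by its probe with the highest mean over the 12 arrays, and 9172 genes had more than 1 probe. No named probe represented Meig1 or Pacrg, so these genes were not analysed here and the knockout could not be checked through its own transcript. The gene table served for names, for gene length and for the order of genes along chromosomes, with no coordinates printed.

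The comparisons were the mutant against wild-type at each age, the difference between those 2 comparisons, and 28 against 22 days within each genotype. A means model over all 12 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend; 8 residual and 0.73 prior degrees of freedom). A gene was called when its two-sided Benjamini-Hochberg adjusted p over 19057 genes was under 0.05. "Rose" and "fell" refer to called genes. Fold changes are on the log2 scale of floored intensities and understate changes of dim genes. The test was checked on simulated data in which 200 of 19057 genes were shifted by a known amount. The shifted genes were drawn only from genes with a mean over 7. The noise was normal, independent between genes and of the same spread in all 4 groups. In the real arrays the spread differed between ages. The SD of an array's deviations from its group, over genes with a mean over 7, was 0.42 to 1.03 at 22 days. At 28 days it was 0.27 to 0.39. The recovery rates therefore do not cover dimmer genes or this unequal spread, and they cannot rank the ages. Shifts of 2 log2 units were recovered for 79.5% of the shifted genes at 22 days between genotypes, 78% at 28 days and 81% between ages in wild-type, with 11, 8 and 20 false calls beside 159, 156 and 162 recovered genes. Shifts of 1 unit were recovered for 29.5%, 29% and 20.5%. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

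Before the data were examined, 21 gene lists were written down: manchette and intramanchette transport; axoneme; outer dense fibre, fibrous sheath and midpiece; nuclear condensation; round spermatid and acrosome; meiotic prophase; piRNA and chromatoid body; spermatogonia. Further lists marked Sertoli cells, Leydig cells, peritubular muscle cells, endothelium, macrophages, red blood cells and epididymis, and the rest covered the interferon response, immediate early genes, heat shock, p53 targets and apoptosis, cholesterol synthesis and ribosomal proteins. Each was tested with camera at a preset correlation of 0.01 and adjusted over the 21 lists, and again with an estimated correlation and with fry, which asks whether a list's genes move one way on balance without comparing them with other genes.

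The rule for naming genes was also fixed then. It takes Spag16 (with Meig1 and Pacrg) in every comparison. It adds the 12 largest rises and falls between genotypes and the 8 largest between ages, among called genes whose arrays did not overlap between the groups. It also takes the 5 smallest p-values where under 5 genes were called, and the 4 largest changes in each called list. Clone and locus names were left out of the ranking, which removed 180 candidate genes from the age comparison in wild-type and 127 in the mutant. Any other gene named was chosen after its values were seen. Alternatives covered the floor, normalization, probe choice, spread estimate, array weights, arrays in the fit, replicate block, set test, threshold, neighbourhood size and leaving out each array, and the closing section gives their effect. In some alternative fits limma warned that it had moved knots of the intensity trend that fell on its boundary, and the original fit gave no such warning.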

Results

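MEIG1 is a small protein of germ cells that binds PACRG at the manchette, the transient skirt of microtubules that surrounds the nucleus of an elongating spermatid. The study asked how the testis transcriptome of mice lacking MEIG1 compares with wild-type at 22 and 28 days of age, a period in which the most advanced germ cells of the juvenile testis pass through the spermatid stages. The data were 12 arrays of total testicular RNA, 3 each for wild-type at 22 days, Meig1-deficient at 22 days, wild-type at 28 days and Meig1-deficient at 28 days. All values below are log2 intensities with a floor of 4, given as mean ± SD over 3 arrays unless stated, and all adjusted p-values come from limma.

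Age set the arrays apart and genotype did not. The leading principal component of 19057 genes held 55.8% of the variance and placed the 6 arrays of 22 days opposite the 6 of 28 days, and the next component held 15.7% and spread the 22-day arrays. Spearman correlations were 0.944 to 0.972 within groups, 0.941 to 0.967 between genotypes of one age and 0.914 to 0.955 between ages. Replicate 1 of the 22-day wild-type group stood apart from the other 2. Its protamine transcript Prm1 was at 8.22, against 14.01 and 13.16 in replicates 2 and 3. Its ribosomal protein genes deviated from the group by a median of -1.503, and its deviations rose with gene length across bright genes (Spearman rho 0.51, across genes, which are not independent replicates). Replicate 3 of the 22-day mutant group also had low ribosomal protein genes, with a median deviation of -1.003.

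**Figure D1:**
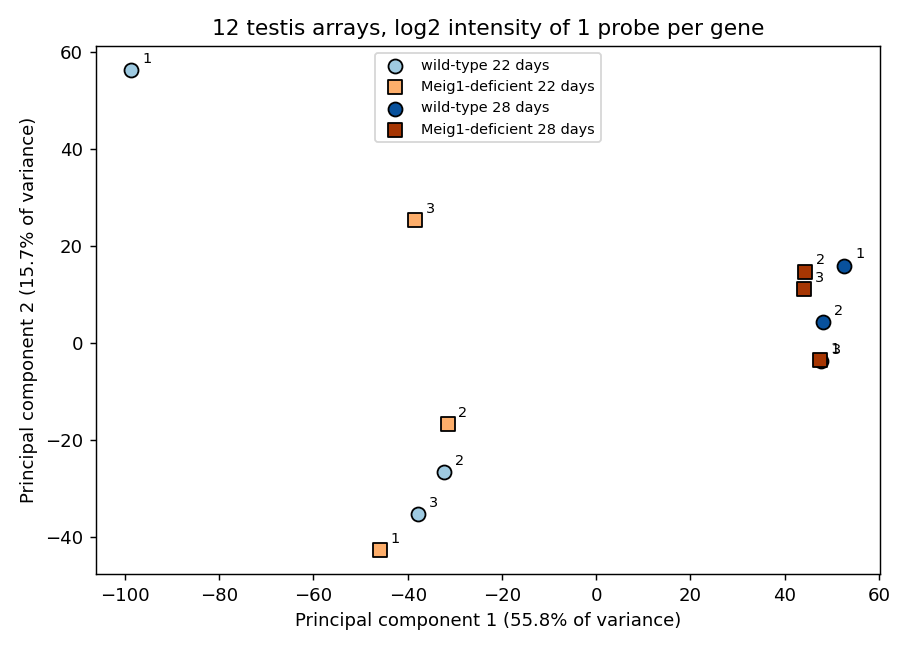
Principal components 1 and 2 (arbitrary units, with the percent of variance on each axis) of the log2 intensities of 12 testis arrays, 1 point per array labelled with its replicate number. The 28-day arrays of both genotypes lie close together at the right, and 22-day wild-type replicate 1 lies far from the other 22-day arrays.

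At 22 days, limma called 2 of 19057 genes between mutant and wild-type testes, both higher in the mutant and both near the floor. Vat1l, a relative of the vesicle protein gene Vat1, lay at the floor in all 3 wild-type arrays and at 4.31 ± 0.06 in the mutant, at least 1.24-fold higher (adjusted p = 0.0134). Pdcl3, a phosducin-like gene whose protein assists the folding of other proteins, was at 4.32 ± 0.145 in wild-type and 5.03 ± 0.11 in the mutant (log2 difference 0.70, SE 0.07, adjusted p = 0.0480). Spag16, which encodes an axoneme protein of the sperm tail, was at 12.09 ± 0.53 and 11.94 ± 0.36, a difference of -0.15 (SE 0.26). Pdcl3 kept its call only without wild-type or mutant replicate 2 of 22 days, among the 12 omissions of 1 array. Vat1l lost it without wild-type replicate 2 of 22 days or any 1 of the 28-day arrays. The next smallest p-values belonged to Tmed5 (at the floor in all wild-type arrays, at least 1.17-fold higher, adjusted p = 0.0938), Hjv (difference 0.98, SE 0.16) and Taf7 (at the floor in 2 of 3 wild-type arrays, at least 1.28-fold higher). All lay at mean levels under 5.3 in both genotypes, and none of these passed. At an unadjusted p under 0.05 there were 412 genes (2.16%), where chance gives a share of 0.05, or less with values tied at the floor. In 589 genes the wild-type and mutant arrays did not overlap. Among the 11476 genes with all 6 arrays above the floor there were 467 of these (4.07%), where chance gives 10%. The count of 2 became 8, 1 and 4 without wild-type replicates 1, 2 and 3, and 6, 8 and 3 without mutant replicates 1, 2 and 3. It was 0 without any 1 of the 28-day arrays, which enter through the shared spread. Both called genes lay at the floor in all 28-day arrays, which lowers that shared spread for them. A fit of the 22-day arrays alone called 0 genes. With the arrays of low ribosomal signal left out (wild-type replicate 1 and mutant replicate 3, a setting added after the data were seen), 13 genes were called, 5 higher and 8 lower, and 0 of them were among the original 2.

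At 22 days 3 of the 21 lists were called between the genotypes, with small medians. The list of outer dense fibre, fibrous sheath and midpiece genes, the accessory structures of the sperm tail, had a median difference of 0.18, with 23 of 34 measured members higher and 8 lower (camera adjusted p = 0.0330; adjusted p = 0.889 with an estimated correlation). Its largest differences were in Smcp, a cysteine-rich protein of sperm mitochondria (0.67, SE 0.46), Oaz3, a spermatid antizyme (0.60, SE 0.49), Spata3 (0.60, SE 0.82) and Spata19 (0.59, SE 0.43). The round spermatid and acrosome list had a median of 0.19, with 25 of 36 members higher (camera adjusted p = 0.0330; adjusted p = 0.889 with an estimated correlation), among them Calr3, a testis chaperone (0.67, SE 0.61), Spaca7 (0.60, SE 0.52) and Spaca4 (0.59, SE 0.51), with Spata16 the other way (-0.61, SE 1.03). The p53 target and apoptosis list was lower, with a median of -0.17 and 13 of 19 members lower (camera adjusted p = 0.0330; adjusted p = 0.515 with an estimated correlation). Its members Pmaip1 (-0.64, SE 0.44), Casp8, an initiator caspase (-0.40, SE 0.26), and Aen (-0.37, SE 0.17) were lower, and Cdkn1a, the cell cycle inhibitor p21, was higher (0.71, SE 0.56). No member of any of the 21 lists rose or fell, either over all genes or adjusted over the list alone. The group mean of the 22-day wild-type includes replicate 1, whose median over the nuclear condensation list was 7.76, against 9.83 and 9.41. Without both wild-type replicate 1 and mutant replicate 3, the setting added after the data were seen, the medians of the sperm-tail and acrosome lists were -0.0246 and -0.036. Without mutant replicate 3 alone the medians of the sperm-tail and acrosome lists were 0 and 0.0037 with the test pointing down. The sperm-tail call also ended without wild-type replicates 1 or 3 or mutant replicate 2, and the acrosome call without wild-type replicate 3 or mutant replicate 2. The p53 call ended without wild-type replicates 2 or 3 or mutant replicates 2 or 3. Median centring and cyclic loess ended the sperm-tail and acrosome calls, and the mean of all probes, a floor of 4 or log2(value + 50) ended all 3.

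The lists closest to MEIG1's site of action showed little difference at 22 days. The manchette and intramanchette transport list had a median of -0.02, with 17 of 41 members higher and 21 lower, and the axoneme list a median of -0.02, with 14 of 41 higher and 22 lower. Nuclear condensation genes, which include the protamines and transition proteins, had a median of 0.34, meiotic prophase -0.06 and piRNA and chromatoid body -0.14. Among somatic markers the medians were 0.05 for Sertoli cells, 0.07 for Leydig cells, -0.10 for peritubular muscle, 0.12 for endothelium, 0.18 for macrophages, 0.13 for red blood cells and 0 for epididymis, and spermatogonia had 0.05. The remaining medians were 0 for the interferon response, 0.06 for immediate early genes, -0.12 for heat shock, -0.02 for cholesterol synthesis and 0.16 for ribosomal proteins. None of these lists passed, and for the manchette list, spermatogonia, Sertoli cells, Leydig cells and epididymis the median, mean and test did not share a sign.

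At 28 days no gene passed between the genotypes. Among genes picked as examples after their values were seen, Odf1 of the outer dense fibres was at 15.18 ± 0.08 in wild-type and 15.13 ± 0.14 in the mutant, Akap4 of the fibrous sheath at 13.57 ± 0.14 and 13.41 ± 0.12, and the protamine Prm1 at 15.58 ± 0.13 and 15.66 ± 0.06. Spag16 was at 11.82 ± 0.15 and 11.74 ± 0.10, a difference of -0.08 (SE 0.26). Hook1, which tethers vesicles to the manchette, was at 10.88 ± 0.43 and 10.86 ± 0.38. Other members of the sperm lists, also chosen after their values were seen, lay further apart without passing: Spaca7 of the acrosome at 10.72 ± 0.26 and 12.26 ± 0.31 (difference 1.54, SE 0.52), and the axoneme gene Cfap69 at 12.17 ± 0.905 and 10.71 ± 2.54 (difference -1.47, SE 1.64). The count by limma was 0 of 19057, with a smallest adjusted p of 0.792. At an unadjusted p under 0.05 there were 284 genes (1.49%), again under the share of 0.05 that chance gives untied values. A floor of 4 called 2 genes and a test of all 45281 probes called 2. The 5 smallest p-values included Clps, a pancreatic-type colipase (at least 1.66-fold lower, with all mutant arrays at the floor), 4930444G20Rik (at least 2.05-fold higher, with all wild-type arrays at the floor) and Cyp4b1-ps2 (difference 0.94, SE 0.16). The others were Adam7, a protease-family gene known from the epididymis (6.57 ± 1.09 in wild-type and the floor in the mutant, at least 5.93-fold lower), and Dkk1, a Wnt antagonist (at least 2.58-fold lower). In 988 genes the genotypes did not overlap, and in 872 of the 11862 genes with all 6 arrays above the floor (7.35%, where chance gives 10%). For 81.0% of the 8564 genes with a mean over 7, the 95% interval of the difference lay within 2-fold either way, against 72.0% at 22 days. Both ages use 1 shared spread per gene, so the median half-width was 0.54 at each. The higher share at 28 days reflects smaller differences (median size 0.085 against 0.183), not tighter intervals. Yet these genes differed between 28-day replicates with an SD of 0.28 to 0.46. For pairs with wild-type replicate 1 of 22 days it was 1.03 and 1.05. The intervals are therefore probably too narrow at 22 days and too wide at 28 days. The simulation shifted only genes with a mean over 7 and gave all groups the same spread. Tested among 19057 genes, shifts of 2 log2 units were recovered for 78% of shifted genes and shifts of 1 for 29%. Leaving out 1 array gave 15 genes (13 lower) without wild-type replicate 1, 3 and 4 without wild-type replicates 2 and 3, and 1, 8 and 4 without mutant replicates 1, 2 and 3.

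**Figure D2:**
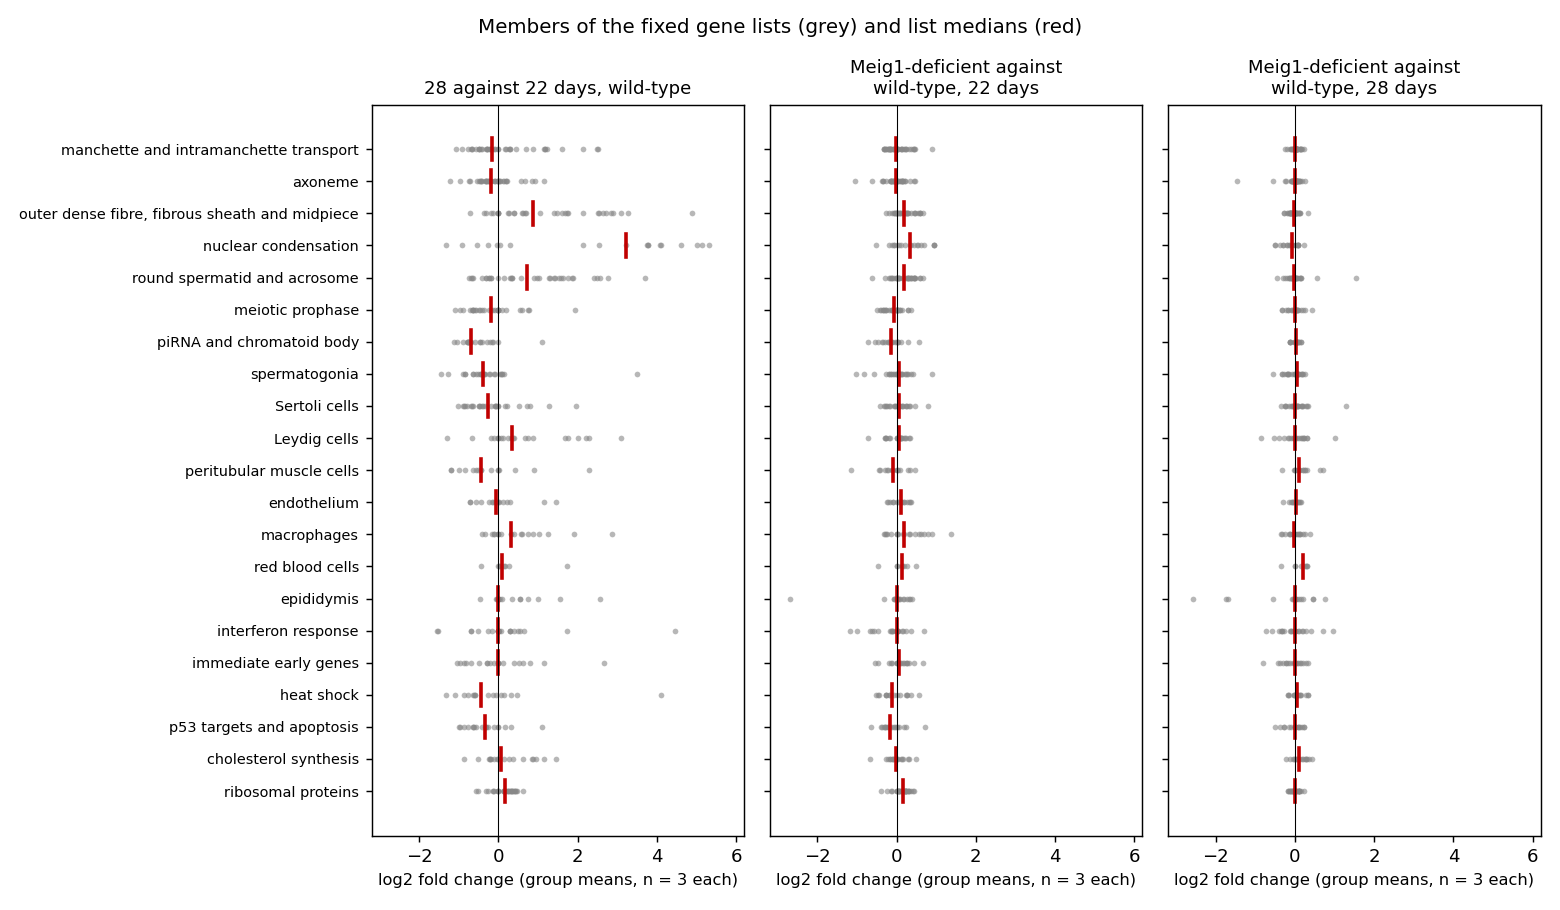
Log2 fold change of each measured member of the 21 fixed gene lists (grey points) and the list median (red bar), for 28 against 22 days in wild-type and for Meig1-deficient against wild-type at each age, from group means of 3 arrays. The median of the nuclear condensation list is 3.22 between ages, and 0.34 and -0.08 between genotypes at 22 and 28 days.

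At 28 days 2 of the 21 lists were called, with small medians. Peritubular muscle cell genes had a median difference of 0.12 with 11 of 16 members higher (camera adjusted p = 0.0217; adjusted p = 0.926 with an estimated correlation), with higher values in the smooth-muscle genes Tagln (at the floor in 2 of 3 wild-type arrays, at least 1.65-fold) and Cald1 (0.63, SE 0.29), both near the floor, and Tpm2 (0.31, SE 0.27), with Dpep1 lower (-0.32, SE 0.40). Cholesterol synthesis genes had a median of 0.10 with 14 of 18 members higher (camera adjusted p = 0.0428; adjusted p = 0.926 with an estimated correlation), led by Insig1, a sterol-regulated gene (0.44, SE 0.32), Sc5d (0.36, SE 0.36), Dhcr7 (0.30, SE 0.40) and Mvd (0.28, SE 0.29). No member of either list rose or fell. Both calls ended without wild-type replicate 1 or 2 or mutant replicate 1 of 28 days or wild-type replicate 1 of 22 days. The cholesterol call also ended without wild-type replicates 2 or 3 or mutant replicate 3 of 22 days, and without mutant replicate 1 of 28 days the cholesterol median was 0.0153 with the test pointing down. Medians of the other lists were 0.01 for manchette and intramanchette transport (22 of 41 higher), 0 for axoneme (19 of 41 higher), -0.03 for outer dense fibre, fibrous sheath and midpiece, and -0.08 for nuclear condensation. They were -0.02 for round spermatid and acrosome, 0 for meiotic prophase, 0.03 for piRNA and chromatoid body and 0.05 for spermatogonia. They were 0.01 for Sertoli cells, 0 for Leydig cells, 0.02 for endothelium, -0.02 for macrophages, 0.20 for red blood cells and 0 for epididymis, and 0 for the interferon response and for immediate early genes, 0.06 for heat shock, 0.0023 for p53 targets and -0.0045 for ribosomal proteins. The median, mean and test did not share a sign for the axoneme, acrosome, meiotic, spermatogonial, Leydig, endothelial, macrophage, p53 and ribosomal lists. Adjusted over the list alone, Tssk1, a spermatid kinase at the floor in all wild-type arrays, was at least 1.47-fold higher and Adam7 at least 5.93-fold lower, and over all genes neither passed.

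Some genes lay lower in all mutant arrays of 28 days than in all wild-type arrays, and a few of these are known from the epididymis. In 18 genes, chosen after their values were seen, every mutant array lay below every wild-type array and the means differed by at least 2 log2 units, while 3 genes met the same criteria in the other direction. They include the beta-defensins Defb22, Defb28, Defb37, Defb38 and Defb43, the protease inhibitor-type genes Wfdc15b, Wfdc16 and Spink10, and Cd52, Rnase12, Cuzd1 and Adam7. Cd52 was at 10.23 ± 0.91 in wild-type and 5.85 ± 0.36 in the mutant, Defb28 at 9.22 ± 1.05 and 4.56 ± 0.61, and Wfdc15b at 8.76 ± 1.07 and the floor, at least 27.1-fold lower. The mean over the 18 genes was 6.36, 8.53 and 8.35 in the wild-type arrays of 28 days and 4.49, 4.47 and 4.62 in the mutant arrays. At 22 days it was 4.93, 6.39 and 4.50 in wild-type and 5.61, 4.41 and 5.36 in the mutant. None of the 18 passed the adjusted threshold with all arrays in the fit. That fit takes each gene's spread from the 22-day arrays too, where the mean over these genes ran from 4.41 to 6.39. A fit of the 28-day arrays alone called 0 of 19057 genes, so none of the 18 passed there either. Without wild-type replicate 1 of 28 days 7 of them passed, namely Adam7 (-3.17, adjusted p = 0.000295), Defb22, Defb43, Ly6f, Serpina16, Spink10 and Wfdc16, and without any other array 0 did.

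**Figure D3:**
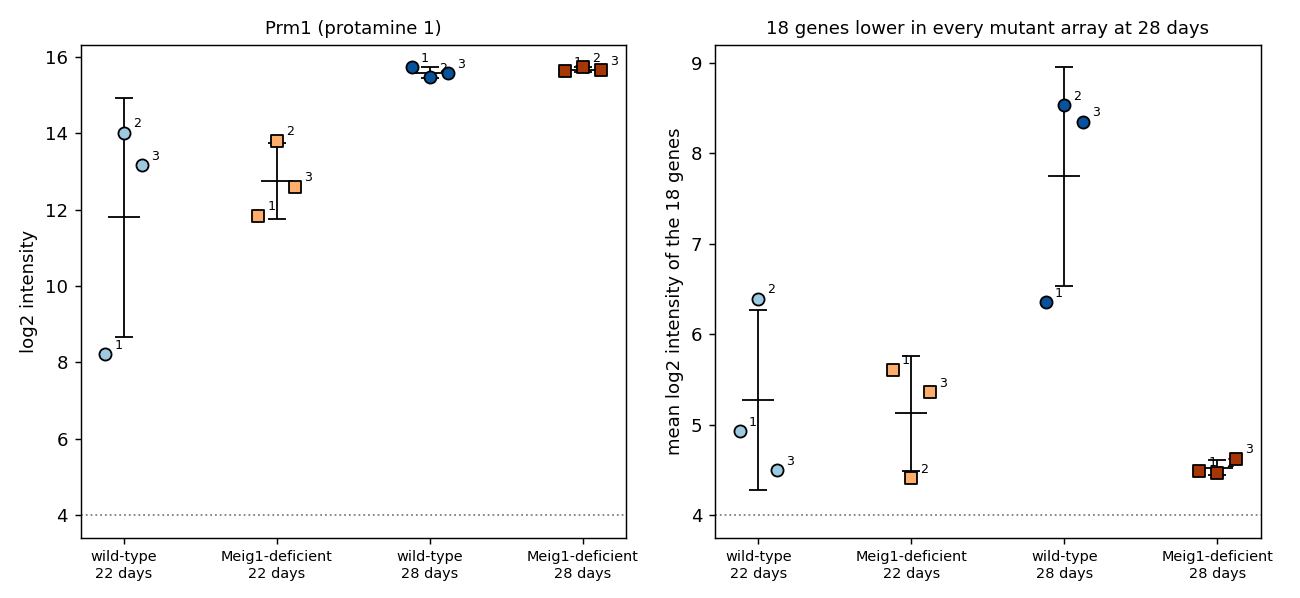
Log2 intensity of Prm1 (left) and the mean log2 intensity of 18 genes that were lower in every mutant array at 28 days (right), 1 point per array with its replicate number, with group mean and SD (n = 3 arrays) and the floor of 4 as a dotted line. Prm1 is at 8.22 in 22-day wild-type replicate 1, and the 18 genes, chosen after their values were seen, lie between 6.36 and 8.53 in 28-day wild-type arrays and between 4.47 and 4.62 in 28-day mutant arrays.

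Whether the genotype difference itself changed with age was tested as an interaction, and no gene passed (0 of 19057 by limma). At an unadjusted p under 0.05 there were 314 (1.65%), under the share of 0.05 that chance gives untied values. The smallest p-values belonged to Vat1l (adjusted p = 0.226), Pdcl3, Hjv (-1.48, SE 0.23), Tmed5 and Il3ra, an interleukin receptor chain (-1.33, SE 0.25). Vat1l and Pdcl3 lay at the floor in all 28-day arrays and Tmed5 in 5 of 6, so for these 3 genes the interaction rests on the 22-day difference. Spag16 gave 0.07 (SE 0.37). The peritubular muscle list was the only list called, with a median of 0.28 and 11 of 16 members higher (camera adjusted p = 0.0269; adjusted p = 0.760 with an estimated correlation). Its largest values were in Cald1 (1.79, SE 0.41), Tagln (1.17, SE 0.59, with 2 of 3 wild-type arrays of 28 days at the floor) and Des (0.51, SE 0.36), with Dpep1 the other way (-0.77, SE 0.56). Adjusted over the list alone, Cald1 rose in this list and 1 gene fell in the epididymis list. The manchette list had a median of 0.06, with a mean of -0.0101, and the axoneme list a median of 0. The count of genes reached 11 without wild-type replicate 1 of 28 days and was 0 only without wild-type replicate 2 of 22 days. It was 5 and 1 without wild-type replicates 1 and 3 of 22 days, and 4, 5 and 2 without mutant replicates 1, 2 and 3 of 22 days. It was 1 and 4 without wild-type replicates 2 and 3 of 28 days, and 1, 1 and 2 without mutant replicates 1, 2 and 3 of 28 days. The list call ended without wild-type replicate 3 of 22 days, mutant replicates 2 or 3 of 22 days, wild-type replicates 1 or 2 of 28 days or mutant replicate 1 of 28 days.

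Between 22 and 28 days many genes were called in the wild-type testis, in both directions. Of 19057 genes, 1171 rose and 1435 fell, and at least 2-fold changes were mostly rises (1011 against 305). The largest rises were in Cstl1, a cystatin-like gene (6.12 ± 1.86 to 12.72 ± 0.06, 97.2-fold), the kallikrein gene Klk1b8 (90.8-fold), Oxct2b and Oxct2a, testis forms of a ketone-body enzyme (90.1-fold and 79.7-fold), Bpifa3 (80.4-fold), Nudt16l2 (77.5-fold), Spata32 (76.7-fold) and Defb33 (71.4-fold). Of these 8 genes, all but Oxct2a lay at the floor in 1 of the 3 arrays of 22 days. All 8 kept their call without any 1 array, but all 8 folds were raised by replicate 1 of 22 days. Without it they were 46.7-fold for Cstl1, 47.5-fold for Klk1b8, 34.8-fold and 32.2-fold for Oxct2b and Oxct2a, 66.1-fold for Bpifa3, 46.3-fold for Nudt16l2, 47.6-fold for Spata32 and 35.2-fold for Defb33. Without replicate 2 of 22 days the log2 rises were 7.29 for Cstl1, 7.40 for Oxct2b, 7.22 for Oxct2a and 6.86 for Nudt16l2. The largest falls were smaller and in dimmer genes. Among them were Chka (-2.54, SE 0.66) and Wars2 (at the floor in 2 of 3 arrays of 28 days, at least 4.78-fold lower), though their other probes did not follow (-0.19 to 0.16). Others were Col1a2, a fibrillar collagen (-2.13, SE 0.56), Resf1 (-2.08, SE 0.44), Alcam (at the floor in 2 of 3 arrays of 28 days, at least 4.11-fold lower), Hs6st2, a heparan sulfate sulfotransferase (-2.03, SE 0.32), Sema3c (-2.00, SE 0.37) and Rubcnl (-1.99, SE 0.55). Wars2, Hs6st2 and Sema3c kept their call without any 1 array. The calls of Resf1 (-1.99 in each case) and Alcam (-2.03 in each case) ended without wild-type replicates 1 or 3 of 28 days. The Chka call ended without wild-type replicate 1 of 22 days (-1.88), wild-type replicates 1 (-2.13) or 3 (-2.41) of 28 days, any mutant array of 22 days or mutant replicates 1 or 2 of 28 days. The Col1a2 call ended without any 1 of the wild-type arrays (-2.28 to -1.97) or mutant replicates 2 or 3 of 28 days. The Rubcnl call ended without any 1 of the 12 arrays (-2.16 to -1.54) except wild-type replicate 1 and mutant replicate 2 of 28 days. Spag16 differed by -0.28 (SE 0.26) and did not pass.

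Part of the genes in each spermatid list rose in wild-type. In the outer dense fibre, fibrous sheath and midpiece list, 18 of 34 genes rose and 0 fell, with a median of 0.87 (camera adjusted p = 8.6e-11; adjusted p = 0.263 with an estimated correlation), among them Spata3 (4.89, SE 0.82), Spata18 (3.27, SE 0.39), Smcp (3.10, SE 0.46) and Ropn1, a partner of the fibrous sheath anchoring proteins (2.90, SE 0.44). In the nuclear condensation list, 10 of 19 rose and 0 fell, with a median of 3.22 (camera adjusted p = 1.9e-06; adjusted p = 0.263 with an estimated correlation), among them Tssk6, a kinase of condensing spermatids (5.33, SE 0.82), the transition protein Tnp2 (5.14, SE 1.03) and the spermatid histones H2al2a (5.02, SE 0.78) and H2al1n (4.62, SE 0.98). In the round spermatid and acrosome list, 16 of 36 rose and 0 fell, with a median of 0.73 (camera adjusted p = 1.3e-06; adjusted p = 0.295 with an estimated correlation), led by Calr3 (3.70, SE 0.61), Fhl5, an activator partner of CREM (2.76, SE 0.39), Tssk2 (2.56, SE 0.36) and Spaca4 (2.49, SE 0.51). The 22-day mean of these lists includes replicate 1, in which Prm1 and the ribosomal protein genes were low. Without it the medians of these 3 lists were 1.00, 2.27 and 0.83 and all were called. The named genes were also still called without it, at 3.76 for Spata3, 3.07 for Spata18, 2.45 for Smcp, 2.30 for Ropn1, 4.28 for Tssk6, 3.79 for Tnp2, 3.93 for H2al2a, 3.26 for H2al1n, 3.02 for Calr3, 2.36 for Fhl5, 2.19 for Tssk2 and 1.81 for Spaca4. Without replicate 2 of 22 days Spata3 was at 5.58, Tssk6 at 5.99, Tnp2 at 5.98, H2al2a at 5.61 and H2al1n at 5.31, and without replicate 3 of 22 days H2al1n was at 5.28. The H2al1n call ended without replicate 1, 2 or 3 of 28 days (4.71, 4.56 and 4.58) and the Spaca4 call without replicate 1 of 28 days (2.30). The piRNA and chromatoid body list was lower, with 6 of 21 genes falling and a median of -0.68, or -0.38 without replicate 1 of 22 days (camera adjusted p = 2.4e-04; adjusted p = 0.295 with an estimated correlation). Gpat2 fell (-0.90, SE 0.15), Rnf17 (-1.12, SE 0.37) and Tdrd5 (-1.04, SE 0.34) did not pass, and Gtsf1 was higher (1.11, SE 0.47) without passing. In the Leydig cell list, 2 of 22 rose and 1 fell, with a median of 0.34 (camera adjusted p = 0.0324; adjusted p = 0.652 with an estimated correlation). Klk1 (3.10, SE 0.63) and the prostaglandin D synthase Ptgds (2.01, SE 0.39) rose, while Insl3 (2.29, SE 0.89) and the testosterone-forming enzyme gene Hsd17b3 (2.22, SE 0.75; at the floor at 22 days, at least 4.66-fold) did not pass. The Leydig call ended without wild-type replicates 1 (median 0.41) or 2 (0.27) of 22 days or replicate 3 of 28 days (0.15), and the Klk1 call without replicate 3 of 28 days (2.91).

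Adjusted over the list alone, 20 sperm-tail, 12 nuclear condensation and 17 acrosome genes rose and 2 of each fell, 9 piRNA genes fell, and 2 Leydig genes rose and 1 fell. The manchette list did not pass as a whole, with 8 of 41 genes rising and 3 falling. Its median was -0.15, but its mean was 0.16 and the test pointed up. The axoneme list (median -0.17) had 3 of 41 rising and 1 falling. Chip and age cannot be told apart, so all age differences include any difference between chips. Rises made up 44.9% of the 2606 calls, and their share moved both ways: it was 35.5% with array weights (1671 rising, 3033 falling), 76.2% in a fit of the 6 wild-type arrays alone (644 rising, 201 falling) and 78.4% after cyclic loess normalization, a setting added after the data were seen (1336 rising, 369 falling). Without wild-type replicates 1, 2 and 3 of 28 days 1300, 1355 and 1399 genes were called, with 836, 840 and 876 rising.

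The mutant testis went through a similar set of changes. Between 22 and 28 days 821 genes rose and 503 fell, with at least 2-fold changes in 750 and 63. The largest rises were in Klk1b8 (65.9-fold), Cstl1 (55.1-fold), Bpifa3 (51.5-fold), Klk1b9 (at the floor at 22 days, at least 47.2-fold), Cyp2a12 (at the floor in 2 of 3 arrays of 22 days and at 9.67 ± 0.09 at 28 days, at least 46.5-fold), Nudt16l2 (45.8-fold), Car2, a carbonic anhydrase (44.7-fold), and Tex46 (43.5-fold). The largest falls were in Scara3 (-2.42, SE 0.40), Dlk1, a Notch-family ligand of immature somatic cells (-2.02, SE 0.27), Nfatc4 (-1.80, SE 0.28), the basement membrane gene Nid2 (-1.71, SE 0.40), Hs6st2 (-1.69, SE 0.32), Gpr146 (-1.69, SE 0.23), Thbs2 (-1.67, SE 0.36) and Hoxb7 (at the floor in 2 of 3 arrays of 28 days, at least 3.10-fold lower). Spag16 differed by -0.21 (SE 0.26). All 8 rises kept their call without any 1 array, though without mutant replicate 1 of 22 days the log2 rises of Klk1b8 and Cstl1 were 5.42 and 5.18, and without mutant replicate 2 of 22 days that of Klk1b8 was 6.70. Among the falls Scara3, Dlk1, Nfatc4 and Gpr146 kept theirs. The Hs6st2 call ended without mutant replicates 1 (-1.65) or 2 (-1.60) of 22 days or replicate 1 of 28 days (-1.49). The Thbs2 call ended without any mutant array of 22 days (-1.75 to -1.63) or mutant replicates 2 (-1.58) or 3 (-1.54) of 28 days. The Nid2 call ended without mutant replicates 1 (-1.52) or 2 (-1.63) of 22 days, any mutant array of 28 days (-1.79 to -1.60), wild-type replicate 3 of 22 days or wild-type replicates 2 or 3 of 28 days. The Hoxb7 call ended without any 1 of the 12 arrays (-1.86 to -1.35) except wild-type replicate 1 of 22 or 28 days.

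The sperm-tail, nuclear condensation and acrosome lists were called in the mutant too (camera adjusted p = 3.4e-11, 4.8e-07 and 4.8e-07), and with an estimated correlation none passed (adjusted p = 0.243, 0.243 and 0.400). Sperm-tail genes rose in 15 of 34 cases (median 0.87), including Akap4 (2.32, SE 0.35), Spata3 (4.12, SE 0.82), Spata18 (2.93, SE 0.39) and Smcp (2.32, SE 0.46). Nuclear condensation genes rose in 8 of 19 cases (median 2.70), including Tnp2 (4.61, SE 1.03), Tssk6 (4.24, SE 0.82) and H2al2a (3.95, SE 0.78), with Tnp1 at 3.69 (SE 1.08) not passing. Acrosome genes rose in 10 of 36 cases (median 0.64), including Calr3 (2.87, SE 0.61), Fhl5 (2.22, SE 0.39), Tssk2 (2.10, SE 0.36) and Capza3 (2.04, SE 0.35). Akap4, Spata18, Fhl5, Tssk2 and Capza3 kept their call without any 1 array. The calls of Spata3 (3.80 to 4.32), Smcp (2.21 to 2.39), H2al2a (3.76 to 4.12), Calr3 (2.34 to 2.97) and Tnp2 (4.05 to 4.77) ended without any 1 mutant array of 28 days or mutant replicate 1 of 22 days. Those of Spata3 and Calr3 also ended without mutant replicate 2 of 22 days, those of Smcp, H2al2a and Tnp2 without mutant replicate 3 of 22 days, and that of Tnp2 without any 1 wild-type array of 28 days. The Tssk6 call (3.75 to 4.30) ended without mutant replicates 1 or 2 of 22 days or 1 or 2 of 28 days.

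Other lists called in the mutant were smaller in effect. piRNA genes fell in 3 of 21 cases (median -0.40, camera adjusted p = 0.00271; adjusted p = 0.406 with an estimated correlation), with Gpat2 (-0.64, SE 0.15) and Tdrkh (-0.58, SE 0.07) falling and Tdrd5 (-0.67, SE 0.34) and Asz1 (-0.60, SE 0.18) not passing. Spermatogonial genes fell in 7 of 27 cases and rose in 1 (median -0.31, camera adjusted p = 0.0206; adjusted p = 0.362 with an estimated correlation). Lin28a (-1.62, SE 0.34) and the GDNF receptor gene Ret (-1.52, SE 0.21) fell, Neurog3 (-1.27, SE 0.33) did not pass, and Lhx1 rose from the floor at least 10.1-fold. In the Leydig list 1 of 22 rose and 1 fell (median 0.31, camera adjusted p = 0.00558; adjusted p = 0.418 with an estimated correlation), with Klk1 rising at least 7.15-fold and Cyp17a1 (2.69, SE 1.15), Hsd17b3 (at least 4.95-fold) and Cyp11a1 (2.25, SE 0.59), enzymes of steroid synthesis, not passing. Klk1 and Hsd17b3 lay at the floor in 2 of 3 arrays of 22 days. Cholesterol synthesis genes rose in 2 of 18 cases (median 0.22, camera adjusted p = 0.00271; adjusted p = 0.400 with an estimated correlation), namely Cyp51 (1.54, SE 0.22) and Insig1 (1.48, SE 0.32), and Sc5d (1.19, SE 0.36) and Dhcr7 (1.09, SE 0.40) did not pass. Adjusted over the list alone, 19 sperm-tail, 11 nuclear condensation and 17 acrosome genes rose and 2 acrosome genes fell. On the same basis 5 piRNA and 9 spermatogonial genes fell and 1 spermatogonial gene rose, 3 Leydig genes rose and 1 fell, and 2 cholesterol genes rose. The spermatogonial call ended without mutant replicate 1 of 22 days (median -0.17), and the Leydig and cholesterol calls without mutant replicate 1 of 28 days (0.01 and 0.10). Tdrkh, Ret, Lhx1 and Cyp51 kept their call without any 1 array. The Gpat2 call ended without any 1 mutant array (-0.69 to -0.56) or wild-type array of 28 days. The Lin28a call ended without mutant replicates 2 (-1.43) or 3 (-1.45) of 22 days or 1 (-1.54) or 2 (-1.55) of 28 days. The Klk1 call ended without mutant replicates 2 or 3 of 22 days (2.57 each), mutant replicates 1 (2.36) or 3 (2.71) of 28 days or any wild-type array of 28 days, and Klk1 was at 3.44 without mutant replicate 2 of 28 days. The Insig1 call ended without any 1 mutant array of 22 days (1.36 to 1.61), mutant replicates 1 (1.35) or 2 (1.24) of 28 days or wild-type replicate 1 of 28 days.

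In the mutant, rises made up 62.0% of the 1324 calls, and falls were in the majority with array weights (3520 calls, 1337 rising, 2183 falling), without wild-type replicate 1 of 22 days (3096 calls, 1157 rising, 1939 falling) and without that array and mutant replicate 3 of 22 days (2937 calls, 1204 rising, 1733 falling). The share of rises was 50.7% in a fit of the 6 mutant arrays alone (654 rising, 635 falling), 88.8% with cyclic loess (972 rising, 123 falling) and 82.6% with log2(value + 50) (978 rising, 206 falling). The count was 782 and 846 without mutant replicates 1 and 2 of 22 days and 706, 687 and 719 without mutant replicates 1, 2 and 3 of 28 days, with 524, 505 and 514 rising.

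The age changes of the genotypes, which share no array but use the same estimate of each gene's spread, overlapped. Of the 821 genes that rose in the mutant, 787 (95.9%) also rose in wild-type, where independent lists of these sizes would share 50.5. Of the 503 that fell, 367 (73.0%) also fell in wild-type, against 37.9 for independent lists. Across genes the changes correlated at Pearson r 0.883, with a slope of 0.74 for the mutant on wild-type, and both comparisons span the same pair of chips. The wild-type change includes the outlying replicate 1 of 22 days, and the slope was not computed without it. It therefore does not show that the mutant changed less. The genotype differences at the 2 ages did not correlate across genes (Pearson r 0.04), and no gene was called at both ages. At an unadjusted p under 0.05 at each age 11 genes differed in the same direction and 12 in opposite directions, against 3.07 for each by independent lists. Because the spread of each gene is shared, a gene with a small spread passes more easily in both comparisons. Independent lists are therefore too low a reference for all these overlaps. For the genotype differences, with 11 genes in the same direction and 12 in opposite directions, the excess does not show a common change. The age changes went largely the same way in separate arrays (Pearson r 0.883), which a shared spread does not produce. That common change may be one of age or of chip.

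Genes next to Meig1 on its chromosome were examined because a targeted mouse line can carry donor-strain sequence there. The window held 105 measured genes, 5 on the side toward the chromosome end and 100 on the other, and 0 were called at either age by limma. At an unadjusted p under 0.05 there were 5 of 105 at 22 days (4.76%, against 2.15% of other genes; Fisher's exact test, two-sided, p = 0.0779) and 4 of 105 at 28 days (3.81%, against 1.48%; Fisher's exact p = 0.0723). Ccdc3, the 17th measured gene from Meig1, was higher in all 3 mutant arrays than in all 3 wild-type arrays at both ages (7.28 ± 0.25 against 7.86 ± 0.05 at 22 days, 6.88 ± 0.24 against 7.30 ± 0.11 at 28 days). Rpp38, a ribonuclease P subunit gene, differed by 0.63 (SE 0.15) at 22 days and 0.20 (SE 0.15) at 28 days, and Olah by 0.28 (SE 0.18) and -0.47 (SE 0.18). These 3 genes were chosen after their values were seen, and none passed.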

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

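The tests on gene length in 22-day wild-type replicate 1, both tests on the 18 genes below and the test of shared chromosomes were chosen only after the results were seen. The difference between ages in the genotype effect on the peritubular muscle list, a median of 0.278, was picked out because the difference was itself tested. Its call rested on camera with a preset correlation and ended with an estimated correlation, with a floor of 64 (median 0.0072) and without each of 6 single arrays named with the comparison. Its largest member, Cald1, was lower in the mutant at 22 days (-1.16, SE 0.29) and higher at 28 days (0.63, SE 0.29), at levels of 4.44 to 5.63.

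Replicate 1 of the 22-day wild-type group lay apart from its group. Loss of short transcripts, in the RNA or in its amplification, predicts a deviation that grows with gene length in genes that do not change with age, and across 2900 such genes Spearman's rho was 0.5323. The trend in this array had been seen before, over a wider set of genes, so this value restates it and leaves the explanation open. An earlier stage of spermatogenesis predicts low levels of age-rising genes beyond those of genes matched on length and level. The 550 age-rising genes were lower by a median of -0.5217 (65.6% of genes lower). A bootstrap over these genes gave a 95% interval of -0.656 to -0.390, but genes of 1 array are not independent replicates. The interval excludes 0 but not the bound of -0.5 set beforehand, and it does not measure the spread between samples. An earlier stage therefore stays open too, and both explanations may hold together. The array's median deviation was -0.75 for the nuclear condensation list but -0.0116 for the round spermatid and acrosome list. It was 0.399 for meiotic prophase, 0 for Leydig cells and -1.503 for ribosomal proteins. These lists were not matched on gene length, so they cannot decide between the explanations. Gene length in the genome was used in place of transcript length.

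The 18 genes were picked for lying lower in every mutant array of 28 days, so their difference there restates the choice. The fixed epididymis list was not called at 28 days (7 of 20 members higher, 6 lower, camera adjusted p = 0.961), and no fixed list or enrichment test ties the 18 genes to the ducts. Tissue of the epididymis or its ducts carried over with the testis may be their source. Over the 22-day arrays, which were not used to pick them, these genes varied together with a mean pairwise correlation of 0.571. Ly6f and Spink10, at the floor in all 22-day arrays, could not enter it. The correlation lay at percentile 100 of 10000 random sets (highest 0.492), which were matched on the 28-day wild-type level and not on the 22-day level. The fixed epididymis list did not follow: of its 11 members more than 2-fold above the floor in a 28-day array, only Adam7 was higher in every wild-type array. Lcn5, Lcn9, Rnase9 and Svs2 were at the floor in every group. Whether the ducts express these members at this age was not measured, so their absence cannot decide the question and carry-over stays open. A difference between the genotypes in the testis or its ducts stays open too, because at 22 days the mean of the 18 genes was 5.27 ± 0.99 in wild-type and 5.13 ± 0.63 in the mutant (exact permutation p = 0.9, two-sided, where 3 against 3 cannot go below 0.1).

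Some genes switched between low and high levels from array to array: of 31 such genes, 16 followed age, 0 genotype and 15 neither, such as Cptp, at 4 in 6 arrays and at 10.7 in the other 6. A cause at the single probe, such as a sequence variant under it, predicts that other probes of the same gene do not follow, and the 7 other probes of 6 of the 15 genes had a median correlation with the switch of 0.1906, with 2 over 0.7, which is consistent with this explanation. Inherited variants shared along a chromosome could not be tested, since no pair of the 15 genes shared a pattern (percentile 0, in random placements as well). No other biological explanation was tested.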

How the results depend on the processing

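The replacement normalizations and scales (cyclic loess, log2(value + 50), centring on the brighter genes, removal of a gene-length trend), the omission of 2 doubted arrays and the unadjusted threshold for neighbours of Meig1 were chosen after the data were seen. Both genes called at 22 days lie near the floor, and the cause of each change below was not tested unless the setting itself gives it (fewer genes, fewer arrays, a stricter threshold). Calls of named genes numbered 68, with a gene called in several comparisons counted in each. They were tested again 1819 times in other settings, passed in 1576 and turned direction in 0. Nearly all were age calls: the only genotype calls among them, Pdcl3 and Vat1l at 22 days, passed in 7 and 12 of 26 tests. The 18 list calls, with a list called in several comparisons counted in each, passed in 412 of 521 such tests and turned in 5. Each age call passed in 18 to 28 of 29 tests and none turned. Between genotypes, the sperm-tail, acrosome and p53 calls at 22 days passed in 15, 17 and 16 of 29. The peritubular and cholesterol calls at 28 days passed in 20 and 13 of 29, and the interaction call in 14 of 28. All 5 turns were in the sperm-tail (2), acrosome (2) and cholesterol (1) lists between genotypes. Results of named genes that had not passed, counted per comparison, were tested again 1481 times, passed in 63 and turned direction in 31. No gene was called at both ages in any setting that gave this count, and the test of all probes did not give it. The 2-fold threshold does not apply to lists, and a fit of only the groups compared does not apply to the interaction.

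At 22 days, the count of 2 genes was 1 without the intensity trend and with quantile normalization repeated, and 0 with only the brighter genes, a floor of 4 or 64, only the groups compared, the 2-fold threshold, log2(value + 50) or the length trend removed. It was 14 with array weights and 13 without the 2 doubted arrays. The 3 called lists became 0 with the mean of all probes, a floor of 4, only the groups compared, the estimated correlation, fry or log2(value + 50), 7 with array weights and 1 without the doubted arrays. Without those arrays, the medians of the sperm-tail and acrosome lists turned to -0.0246 and -0.036. At 28 days, the count of 0 genes was 2 with a floor of 4 and with all probes. The 2 called lists became 1 with a floor of 4 or 64 or the length trend removed, and 0 with array weights, the estimated correlation, fry or without the doubted arrays. In the interaction, the count of 0 genes was 4 with array weights, 8 without the doubted arrays and 1 when centred on the brighter genes. Its 1 called list became 0 with the mean of all probes, a floor of 4, the estimated correlation, fry, the length trend removed or the doubted arrays out. It became 2 with only the brighter genes, a floor of 64 or log2(value + 50), 3 with median centring, 4 with cyclic loess and 6 with array weights.

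Between ages, the wild-type count of 2606 was 4704 with array weights, 845 with only the groups compared, 1316 at 2-fold and 1705 with cyclic loess, and the mutant count of 1324 was 3520 with array weights, 813 at 2-fold and 2937 without the doubted arrays. Both age comparisons had 0 lists called with the estimated correlation and 7 each with fry. Among neighbours of Meig1, 8 genes passed an unadjusted p, in place of 0.

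Leaving out each array in turn gave 0 to 8 genes and 0 to 7 lists at 22 days, 0 to 15 genes and 0 to 3 lists at 28 days, and 0 to 11 genes and 0 to 5 lists in the interaction. It gave 1300 to 2691 genes and 4 to 6 lists between ages in wild-type, 687 to 3096 genes and 5 to 9 lists in the mutant, 0 to 0 genes called at both ages, and 0 to 1 neighbours of Meig1. Without mutant replicate 3 of 22 days the sperm-tail and acrosome medians were 0 and 0.0037 with the direction turned, and without mutant replicate 1 of 22 days they were 0.3328 and 0.4043. The cholesterol median at 28 days was 0.189 without mutant replicate 2 of 28 days, and without mutant replicate 1 of 28 days it was 0.0153 with the test pointing down.

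The replicate numbers did not pair the samples. Deviations of same-numbered arrays correlated between genotypes at -0.34, 0.28 and -0.59 at 22 days and -0.30, 0.00 and -0.22 at 28 days, and between ages at 0.08, -0.06 and 0.20 in wild-type and 0.22, 0.03 and 0.17 in the mutant, and not every sample correlated best with its own number. With the number as a replicate block, 0 genes were called at 22 days, 1 list at 28 days, 4 lists in the interaction, 1228 genes (789 rising, 439 falling) and 8 lists between ages in wild-type and 377 genes (266 rising, 111 falling) in the mutant.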

Other observations

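The tests on other splits of the samples were set beforehand, and the genes named in this part were chosen after their values were seen. Outside the called lists, single members of several lists changed with age in both genotypes. Aif1, a macrophage gene, rose by 2.86 (SE 0.34) in wild-type and 2.18 (SE 0.34) in the mutant, and the antigen presentation gene H2-Eb1 rose in wild-type (1.91, SE 0.36). Alas2, of red cell heme synthesis, rose by 1.74 (SE 0.18) and 1.59 (SE 0.18), the testis-specific heat shock gene Hspa1l by 4.11 (SE 0.50) and 3.59 (SE 0.50), Xaf1 by 4.46 (SE 0.84) and 3.69 (SE 0.84), Jund by 2.66 (SE 0.345) and 2.38 (SE 0.345), and the smooth-muscle actin Actg2 by 2.28 (SE 0.25) and 2.08 (SE 0.25). Of the manchette list, Hook1 rose by 2.13 (SE 0.34) and 2.44 (SE 0.34) and Tbc1d21 by 2.52 (SE 0.30) and 1.91 (SE 0.30). Among Sertoli cell genes Dhh fell in both genotypes (-0.43, SE 0.07, and -0.33, SE 0.07), and Fshr (-0.86, SE 0.21) and Gata1 (-0.69, SE 0.19) fell in wild-type. Rpl3 fell in both (-0.57, SE 0.08, and -0.46, SE 0.08), the only member of 34 in the ribosomal protein list that changed.

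Counts in wild-type for lists that did not pass were 1 of 31 meiotic prophase genes rising and 2 falling, 1 of 27 spermatogonial genes rising and 7 falling, 3 of 28 Sertoli genes falling, 1 of 16 peritubular genes rising and 3 falling, and 1 of 16 endothelial genes rising and 2 falling. In the macrophage list 2 of 20 rose, in the red blood cell list 1 of 8, in the epididymis list 1 of 20 (Adam7), and in the cholesterol list 2 of 18, with 0 falling in each. Interferon response genes rose in 2 of 25 cases and fell in 2, immediate early genes rose in 2 of 21, heat shock genes rose in 1 of 16 and fell in 3, and p53 targets fell in 3 of 19. In the mutant, manchette genes rose in 5 of 41 cases, axoneme genes in 1 of 41, interferon response genes in 2 of 25, and 1 gene each in the peritubular, macrophage, red blood cell and heat shock lists. Immediate early genes rose in 2 of 21 cases and fell in 1, and 1 of 28 Sertoli genes and 1 of 34 ribosomal protein genes fell. No gene was called in the meiotic prophase, endothelial, epididymis or p53 lists of the mutant.

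The 28-day difference of the acrosome gene Spaca7, 1.54, had a 95% interval of 0.345 to 2.73 before adjustment and did not pass. At 22 days its difference was 0.60 (SE 0.52).

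Other splits of the 6 arrays in each comparison number 10 with the real one, too few for a share under 0.05. For genes at 22 days, 8 of 10 splits gave at least the real count of 2 (highest other 5), and for lists 9 of 10 gave at least 3 (highest other 11). At 28 days, 10 of 10 gave at least 0 genes, as any count does (highest other 8), and 8 of 10 at least 2 lists (highest other 10). Between ages, 1 of 10 splits, the real one, reached 2606 genes in wild-type (highest other 1) and 1 of 10 reached 1324 in the mutant (highest other 3), while for lists 9 of 10 reached 5 in wild-type (highest other 10) and 7 of 10 reached 7 in the mutant (highest other 13). A split of the 22-day arrays into wild-type replicate 1 with mutant replicates 2 and 3 against the rest gave 3256 genes at an unadjusted p under 0.05, against 412 for the genotypes, which points to a structure of those samples other than genotype.

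For the interaction, 97 of 100 drawn splits within both ages gave at least the 1 list called (highest other 15), so chance cannot be excluded there. The real count was 0 for interaction genes (highest other 7), for genes called at both ages (highest other 1) and for neighbours of Meig1 (highest other 1). All 100 of 100 splits reach a count of 0, whatever the data, so these splits say nothing about chance. No probe separated all 6 wild-type from all 6 mutant arrays by a wide gap: the widest was 0.3232 log2 units, for an unnamed probe, and 89 of 200 splits within both ages gave a gap as wide (highest other 4.024), so chance cannot be excluded there. In all, 10 probes separated the genotypes, against a median of 16 in the other splits, while 6054 separated the ages.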
